A study of Arabidopsis thaliana with 24 samples.

How the data were processed

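Values were analysed as the authors deposited them: linear signal intensity per probe set, computed with the MAS5 algorithm per the submitters' processing notes. The MAS5 version and the target of its scaling are not given in the sources used here; the trimmed mean of each array lay between 99.96 and 99.97. Labelled RNA was made from total RNA with biotin, per the labels' protocols. Of 22810 probe sets, 64 control probe sets were left out, which left 22746.

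From these values, log2(signal + 7.72) was taken, the pseudocount being the 20th percentile of all signals. It pulls folds of weak signals toward 0, so the log2 changes understate the change of genes near the floor. Probe sets above the 40th percentile of their own array on at least 2 of the 24 arrays were tested, 16814 in number, and 5932 were left out. Limma 3.58.1 in R 4.3.3 was fitted with 12 group means and a variance trend with intensity, on 12 residual degrees of freedom and 5.28 prior ones. Each time was compared with 0.5 h in each tissue, roots with shoots over the mean of the times, and the root change with the shoot change at each time. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets in each comparison, with a threshold of 0.05. Standard errors come from limma, and SDs of signals are over the 2 arrays of a group.

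The annotation used here named genes for 14016 probe sets: 13513 for 1 gene and 503 for several; 8730 had no name in it. Of the 13513, 13436 matched the TAIR10.1 gene table, in 13356 genes, and 77 kept their own symbol. Of the tested probe sets, 9206 named 1 gene, in 9099 genes. Gene lists were fixed before the data were examined, as were the comparisons, the rule for naming genes, the filter, the pseudocount and most alternatives. The 28 pathway lists and 2 marker lists held 528 genes, of which 93 were named here. At least 3 genes were tested for 12 pathway lists and fewer for 16, and 11 of those had none. Tested were 5 of the 27 genes fixed as ABA- and dehydration-induced, 11 of 51 of photosynthesis and 21 of 51 for ribosomal proteins. Of heat shock 3 of 19 were tested, of phenylpropanoid and flavonoid synthesis 3 of 20, and of senescence and carbon starvation 4 of 15. A list result holds for the tested genes only. The minimum of 3 was chosen after the annotation and before the values were seen. Camera tested each list against the other genes with a preset correlation of 0.01, the brightest probe set per gene and Benjamini-Hochberg adjustment over the lists in a comparison. The test was repeated with a correlation estimated from the residuals, and fry tested whether the genes of a list moved on balance one way.

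Genes were named by a rule. Among probe sets naming exactly 1 gene, past an adjusted p of 0.05 and with both arrays of one group above both of the other, the 10 largest rises and 10 largest falls were taken at 24 h in each tissue. At 1, 3, 6 and 12 h the 3 largest each way were taken. Between roots and shoots 10 each way were taken, with all 12 arrays of one tissue above all 12 of the other. For the tissue difference at 24 h 5 each way were taken without the rule on overlap. Any member of a fixed list could also be named. Gene families, taken from gene symbols with at least 5 tested members, 26 in number, were added later, and their members lie outside the rule and were chosen after their values were seen.

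The fit was tried on simulated arrays in the shoot comparison of 24 h with 0.5 h, with 16814 probe sets. Known changes were put into 200 of them. Noise was drawn independently for each probe set, with an SD that followed mean signal alone, unlike in the real arrays. The fit recovered 14 of 50 changes of 0.5 in log2, 46 of 50 of 1, 49 of 50 of 2 and 50 of 50 of 4, with 5 calls among 16614 unchanged probe sets. In the real comparison 9854 probe sets passed, so the threshold allowed larger unadjusted p-values there. These counts of recovered and false calls therefore do not carry over to it. Of 200 lists of 20 unchanged genes in the same comparison, drawn from 9099 genes, camera gave 5 an unadjusted p under 0.05 and 0 an adjusted one. The simulated genes were not correlated, so this cannot show how camera behaves where the genes of a list move together.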

Results

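Gene expression was measured on 24 arrays in Arabidopsis thaliana, accession Col-0, during treatment with 300 mM mannitol, a sugar alcohol that makes water harder for plants to take up. Shoots and roots were sampled after 0.5, 1, 3, 6, 12 and 24 h, with 2 arrays for each tissue and time and so 12 arrays per tissue. The plants were 16 days old and the treatment began 3 h into a 16 h light period. Time in mannitol therefore moved with time of day, except that the 24 h samples were taken at nearly the same clock time as the 0.5 h samples. Each time was compared with 0.5 h in the same tissue; untreated plants were not analysed here, so a change stands for the course over time in mannitol and not for treated against untreated plants. The labels do not say that the 2 replicates came from separate cultures, so the p-values measure only the spread between these samples.

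Replicate arrays correlated across probe sets with Pearson's r of 0.973 to 0.983, and no pair held identical values. The number of arrays limits the precision of every value. The median signal, in array units, lay between 31.4 and 48.3 over the 24 arrays. Its group mean was 39.0 in shoots at 0.5 h and 33.5 at 24 h, and 48.3 and 43.2 in roots at the same times. The arrays carry 2 designs of the actin control, and the ratio of its 3' to its 5' probe sets is a sign of RNA quality. In the first design this ratio averaged 6.77 ± 0.499 (SD, n = 2) in shoots at 0.5 h, 10.3, 12.1 and 12.8 at 3, 6 and 12 h, and 16.7 ± 3.21 at 24 h, while its group means in roots lay between 11.1 and 12.3. In the other design it averaged 2.42 in shoots at 0.5 h and 2.57 at 24 h, and in roots 1.74 ± 0.00738 at 0.5 h, 2.14 ± 0.00548 at 3 h and 1.96 ± 0.0956 at 24 h. The GAPDH ratio averaged 1.35 in shoots at 0.5 h, 1.73 ± 0.0178 at 6 h and 1.57 ± 0.220 at 24 h, and in roots 1.104 ± 0.00130 at 0.5 h, 1.35 ± 0.536 at 6 h and 1.34 ± 0.125 at 24 h. Ranks by size hold for log2(signal + 7.72), and genes with a signal below 7.72 in one group, such as AT3G17520 and AT1G23130, can change places with others on another scale.

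In shoots, genes for late embryogenesis abundant proteins and dehydrins, which protect cells that lose water, were among those that rose most between 0.5 h and 24 h. AT3G02480, for a late embryogenesis abundant protein, rose by 9.11 ± 0.34 in log2 (SE; adjusted p = 4.8e-12), from a signal of 2.62 ± 3.05 (SD, n = 2) to 5616 ± 685. AT3G17520, of the same kind, rose by 9.07 ± 0.31 and LEA4-5 by 8.15 ± 0.37. The dehydrin gene LTI30 rose by 6.88 ± 0.46, to a signal of 4643, and COR15A, for a protein that protects chloroplasts in the cold, by 6.45 ± 0.51, to 3013. AT2G10940 was among the genes that fell most, from a signal of 1979.9 ± 121 to 25.04 ± 31.5, a change of -6.37 ± 0.48; it was -5.17 without shoots 24 h replicate 1 and -7.57 without replicate 2. This comparison asks how far shoot expression had moved after a day, with the clock time nearly matched. The first-design actin ratio of the shoot arrays had moved as well, from 6.77 to 16.7, but the other actin ratio (2.42 to 2.57) and the GAPDH ratio (1.35 to 1.57) by less.

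The other 5 of the 10 largest rises in shoots at 24 h were AT2G42560 (7.17 ± 0.45), AT3G57010 (7.14 ± 0.35), AT2G41190 (6.84 ± 0.28), AT5G50360 (6.58 ± 0.32) and AT5G39520 (6.49 ± 0.28). The other 9 of the 10 largest falls ran from AT5G48490 (-5.59 ± 0.30) through AT1G22690 (-5.14), AT5G44020 (-5.10), TBL45 (-4.83), AT3G06070 (-4.79), AT1G29660 (-4.58), AT1G09750 (-4.38) and AT1G04040 (-4.38) to AT1G66100 (-4.303 ± 0.31). Without shoots 24 h replicate 1 the falls were smaller for AT5G48490 (-4.97), AT1G22690 (-4.14), TBL45 (-4.13) and AT1G04040 (-3.75), and without replicate 2 larger (-6.20, -6.14, -5.53 and -5.01). AT2G42560 and AT5G50360 rose by 6.56 and 5.90 without replicate 1 and by 7.79 and 7.26 without replicate 2. In all, 9854 of 16814 probe sets passed an adjusted p of 0.05 in limma, 4279 higher and 5575 lower, and 2034 and 2652 of these differed by at least 2-fold. The median of all probe sets was -0.12. Under quantile normalization, which brought that median to -0.02, 4504 were higher and 4818 lower.

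All 5 tested genes, of 27 on the list of ABA- and dehydration-induced genes, rose in shoots from 3 h on, and 5 of 5 passed adjusted over the list alone. Their median change was 5.19 at 3 h, 6.47 at 6 h, 6.20 at 12 h and 6.45 at 24 h, with adjusted p of 4.1e-08, 7.1e-07, 7.3e-06 and 5.8e-05 in camera's test of the list against the other genes; at 24 h, adjusted p = 0.166 with an estimated correlation. The earlier calls were lost too, with adjusted p = 0.111 at 3 h, 0.138 at 6 h and 0.155 at 12 h with an estimated correlation. COR47, a dehydrin gene, rose by 3.85 ± 0.25 at 24 h, from a signal of 293 to 4374. COR15B reached 6.14 ± 0.36 above its 0.5 h value at 6 h and stood 1.70 ± 0.36 above it at 24 h. At 1 h the list had already passed camera (median 0.89, adjusted p = 0.0144; adjusted p = 0.721 with an estimated correlation), though not fry (0.185). COR15A (2.65 ± 0.51) and COR15B (1.48 ± 0.36) were the 2 members that rose at 1 h, also 2 adjusted over the list alone. Without shoots 1 h replicate 1 neither passed (1.78 and 0.82, adjusted p 0.0604 and 0.241), without replicate 2 they were at 3.53 and 2.14, and COR15B did not pass without shoots 0.5 h replicate 2 either (0.124).

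**Figure D1:**
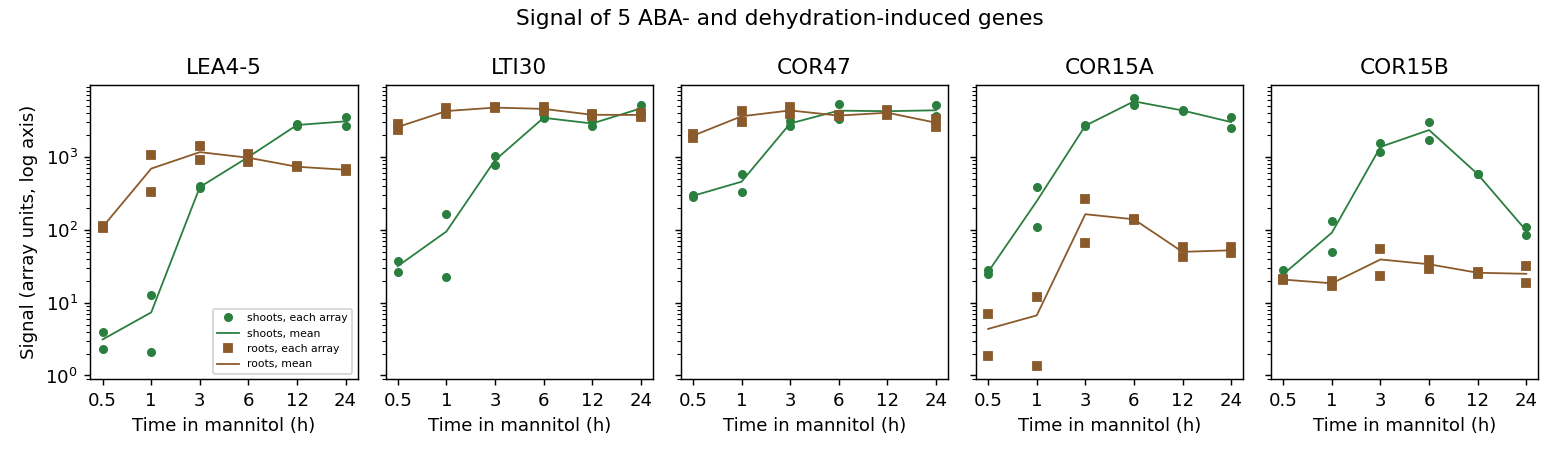
Signal in array units on a log axis against hours in mannitol for 5 ABA- and dehydration-induced genes, with 1 point per array and lines through the group means, for shoots and roots. In shoots all 5 genes stood above their 0.5 h signal from 3 h on; in roots LTI30 (2581 at 0.5 h) and COR47 (1957) were high from the first time on, while COR15A went from 4.36 at 0.5 h to 52.3 at 24 h, with 262 on its highest array, at 3 h.

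Genes for cytosolic ribosomal proteins fell in shoots. Of 21 tested, 17 fell at 3 h, 19 at 6 h, 19 at 12 h and 20 at 24 h, against 20, 19, 19 and 20 adjusted over the list alone. The median changes were -0.60, -1.08, -1.09 and -1.41, with camera adjusted p of 4.9e-07, 2.3e-09, 1.0e-07 and 2.7e-09; with an estimated correlation none passed (adjusted p = 0.272, 0.138, 0.159 and 0.166 with an estimated correlation). AT2G19730 (-2.22 ± 0.13) and AT5G07090 (-2.14 ± 0.15) fell furthest at 24 h, and AT4G02230 was the member that did not pass (-0.06 ± 0.10). Photosynthesis genes fell later: 10 of 11 were lower at 12 h and 10 at 24 h, as many adjusted over the list alone, with medians of -0.86 (-0.51 under quantile normalization) and -0.98. Camera gave the photosynthesis list an adjusted p of 9.9e-05 at 12 h and 0.00159 at 24 h (adjusted p = 0.159 and 0.280 with an estimated correlation). PSBY, for a photosystem protein, fell by 1.74 ± 0.18 and the light-harvesting gene LHCB4.1 by 1.18 ± 0.16 at 24 h, while RCA, for Rubisco activase, was 0.22 ± 0.15 lower and did not pass.

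Genes of phenylpropanoid and flavonoid synthesis rose in shoots at 12 h (median 1.45, camera adjusted p = 0.0459) and 24 h (1.46, 0.0464), with adjusted p = 0.334 and 0.280 with an estimated correlation. All 3 tested members rose at 24 h, 3 adjusted over the list alone: AT4G14090 by 3.37 ± 0.46, DFR, for dihydroflavonol reductase, by 1.46 ± 0.36 and UF3GT by 1.43 ± 0.23. The 24 h list call was lost under quantile normalization, without a pseudocount, with the stricter filter on low signal and with lists of 1 or 2 genes also tested, and the 12 h call under the last 3 of these. In roots the list did not pass at any time (median 0.68 and adjusted p = 0.174 at 24 h). Heat shock genes rose in shoots at 24 h, 3 of 3 and 3 adjusted over the list alone, with a median of 2.22 (camera adjusted p = 0.0464; adjusted p = 0.280 with an estimated correlation). AT1G53540 rose by 2.72 ± 0.57, AT5G48570 by 2.22 ± 0.42 and ATHSP22.0 by 2.12 ± 0.35; AT1G53540 was at 2.12 without shoots 24 h replicate 1 and at 3.32 without replicate 2. That list call was lost under the same 4 alternatives and with 4 times the pseudocount.

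Genes for xyloglucan endotransglucosylases, which loosen and remodel cell walls, fell in shoots: 5 of 6 tested were lower at 12 h, 5 adjusted over the list alone, with a median of -1.55 (camera adjusted p = 0.00771; adjusted p = 0.112 with an estimated correlation). At 24 h 5 were lower, but the list missed the threshold (median -1.23, adjusted p = 0.0517), with XTH16 at -3.50 ± 0.29 and XTH18 at -2.82 ± 0.43. Expansin genes, whose products also loosen walls, went both ways at 24 h: 2 of 11 rose and 5 fell, 7 adjusted over the list alone, with a camera adjusted p of 0.694. EXLB1 rose by 4.92 ± 0.33, from a signal of 45.0 to 1563, and EXPA8 fell by 4.23 ± 0.50. EXPA16 stood 4.85 ± 0.33 above its 0.5 h value at 6 h and 2.58 ± 0.33 at 24 h. At 6 h the expansin median was -0.15 and the mean 0.38, and at 12 h -0.22 and 0.25, so their signs differed (camera adjusted p = 0.665 and 0.702).

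Of the 4 genes of senescence and carbon starvation, SAG29, for a sugar transporter, rose by 5.37 ± 0.32 in shoots at 24 h and IVD, of leucine breakdown, by 1.84 ± 0.24. These were also the 2 called adjusted over the list alone, and camera did not call the list (median 1.14, adjusted p = 0.0714). The 3 cell cycle genes had a median of -0.89 (camera adjusted p = 0.432), with TOPII at -1.91 ± 0.41 and AUR1 at -0.89 ± 0.24, also the 2 called adjusted over the list alone; without shoots 0.5 h replicate 1 TOPII was at -1.09 (-2.72 without replicate 2) and AUR1 did not pass (adjusted p 0.109). Among 6 auxin-response genes 1 rose and 1 fell, with 1 call adjusted over the list alone; the median was -0.18 and the mean -0.01, while camera's direction was up (adjusted p = 0.906). GH3.3 was 1.01 ± 0.32 higher and IAA29 0.80 ± 0.31 lower, and neither passed without shoots 0.5 h replicate 2 (adjusted p 0.0835 and 0.264) or shoots 24 h replicate 2 (0.154 and 0.253). IAA29 also missed the threshold under quantile normalization (0.120), under median scaling (0.0583), without a pseudocount (0.0506) and in a fit of shoot arrays alone (0.0565). GH3.3 missed it with 4 times the pseudocount (0.0619).

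Touch and wounding genes did not pass as a list in shoots at 24 h (median 0.54, adjusted p = 0.622), and of 3 members WRKY6 was higher (1.27 ± 0.43). Its call was lost without shoots 0.5 h replicate 1 (change 0.32, adjusted p 0.480), without shoots 24 h replicate 2 (0.0850) and in a fit of shoot arrays alone (0.0722), and without shoots 0.5 h replicate 2 the change was 2.21. Of 5 reference genes, AT2G28390 (0.59 ± 0.14) and PEX4 (0.40 ± 0.13) rose and AT4G26410 fell (-0.46 ± 0.11) in shoots at 24 h, 3 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.432). PEX4 did not pass without shoots 0.5 h replicate 1 (0.0742) or shoots 24 h replicate 1 (0.199). PYK10, a marker of root tissue fixed beforehand, fell in shoots by 1.37 ± 0.17 between 0.5 h and 24 h, from a signal of 947 to 361, and was lower at each time from 1 h on.

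At 1 h in shoots AT2G20670 was already lower (-5.71 ± 0.35, adjusted p = 1.7e-08), its signal having gone from 1548 to 21.9. AT1G33055 (-4.66 ± 0.46) and AT5G61590 (-4.27 ± 0.21) were the next largest falls, and AT1G20070 (3.43 ± 0.36), AT5G15950 (3.19 ± 0.20) and AT5G12940 (3.05 ± 0.27) the largest rises. In all 1480 probe sets passed at 1 h, 716 higher and 764 lower; AT5G12940 was at 2.44 without shoots 0.5 h replicate 1 and at 3.66 without replicate 2, and the number of probe sets was 856 without shoots 0.5 h replicate 2, and 931 and 935 without shoots 1 h replicates 1 and 2.

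At later times AT3G02480 rose in shoots by 6.49 at 3 h, 8.25 at 6 h and 8.88 at 12 h. COR15A (6.31 ± 0.51) and PUB19, for a ubiquitin ligase (5.57 ± 0.25), were the next named at 3 h, COR15A (7.41) and LEA4-5 (6.54) at 6 h, and AT3G17520 (8.44) and LEA4-5 (7.99) at 12 h; without a pseudocount AT3G17520 stood above AT3G02480 at 12 h. The falls were led at 3 h by AT1G33055 (-4.55), AT5G19120 (-4.11 ± 0.36) and AT2G20670 (-3.66). AT2G10940 (-4.71), AT5G44020 (-4.49) and AT5G48490 (-4.43) led them at 6 h, and the same 3 genes at 12 h (-5.18, -5.32 and -5.68). At 6 h AT5G44020 was at -5.16 without shoots 6 h replicate 1 and at -3.81 without replicate 2. The clock gene GI, which peaks late in the day, was 2.98 ± 0.13 above its 0.5 h value at 6 h and 0.22 ± 0.13 above it, without passing, at 24 h. Calls numbered 5985 at 3 h (2846 higher, 3139 lower), 8093 at 6 h (3826 and 4267) and 8904 at 12 h (4297 and 4607).

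**Figure D2:**
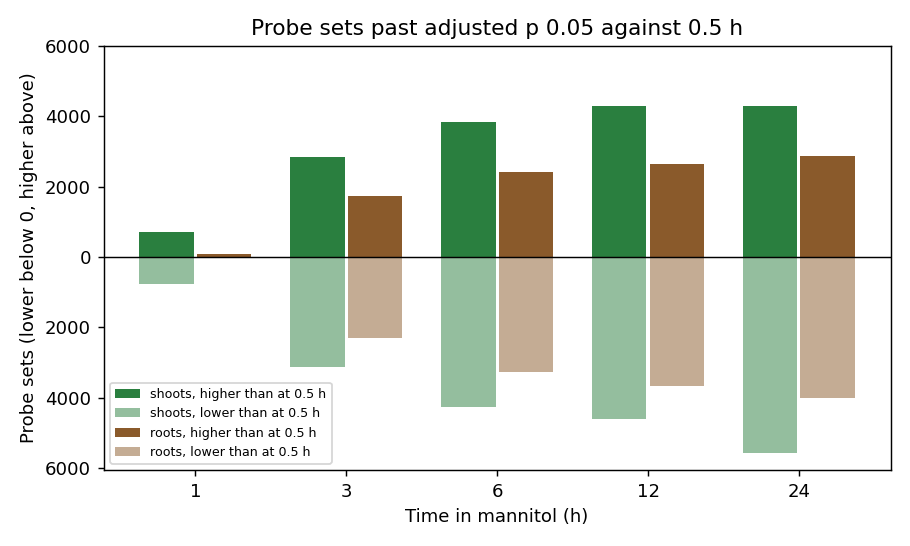
Number of probe sets past an adjusted p of 0.05 against 0.5 h, by hours in mannitol, with those higher drawn above 0 and those lower below, for shoots and roots. Shoots had 1480 at 1 h and 9854 at 24 h, and roots 124 and 6868.

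In roots AT5G28520 rose at 24 h by 7.02 ± 0.30 (adjusted p = 2.4e-10), from a signal of 3.77 to 1484, and AT3G17520, a late embryogenesis abundant gene, by 6.40 ± 0.31, from 3.71 to 954. The small heat shock protein genes AT1G53540 (5.12 ± 0.57) and ATHSP22.0 (4.77 ± 0.35) and the sugar transporter gene SAG29 (4.84 ± 0.32) were among the 10 that rose most. BCAT4, of glucosinolate synthesis, fell furthest, from a signal of 994 to 51.2, a change of -4.095 ± 0.29 (adjusted p = 4.4e-08). The question is the same as in shoots, how far expression had moved after a day. The second actin ratio of the root arrays went from 1.74 to 1.96 and their GAPDH ratio from 1.104 to 1.34 over that interval.

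The other rises named for roots at 24 h were AT2G37870 (5.44 ± 0.29), AT3G02480 (4.94 ± 0.34), BGLU24 (4.89 ± 0.37), AT4G33550 (4.75 ± 0.28) and AT5G07330 (4.298 ± 0.32). The other falls were those of the glutathione transferase gene GSTU20 (-3.65 ± 0.45), AT4G24780 (-3.56), AT4G01390 (-3.52), AT3G01260 (-3.30), AT2G19970 (-3.14), AT1G73600 (-2.93), the expansin gene EXPB3 (-2.92), AT3G10720 (-2.90) and the endoglucanase gene GH9B13 (-2.84 ± 0.26); AT3G10720 was at -2.10 without roots 24 h replicate 1 and at -3.69 without replicate 2. In all 6868 probe sets passed, 2866 higher and 4002 lower, and 1080.0 and 1262 of these differed by at least 2-fold; under median scaling 3434 were higher and 3237 lower, so the balance turned.

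Heat shock genes rose in roots, 3 of 3 at 6, 12 and 24 h and 3 adjusted over the list alone, with medians of 3.09, 4.59 and 4.77. Camera gave adjusted p of 0.00163, 2.8e-04 and 3.9e-04 (adjusted p = 0.189, 0.141 and 0.104 with an estimated correlation). AT5G48570 rose by 1.88 ± 0.42 at 24 h. Genes of senescence and carbon starvation rose at 3 h (3 of 4, with 4 adjusted over the list alone) and at 6, 12 and 24 h (4 of 4 each way of adjusting). Their medians were 1.65, 1.91, 2.18 and 2.14, with camera adjusted p of 2.4e-04, 1.2e-04, 8.2e-05 and 2.7e-05; adjusted p = 0.134, 0.0883, 0.0784 and 0.0785 with an estimated correlation. At 24 h the leucine breakdown genes IVD (2.37 ± 0.24), MCCA (1.92 ± 0.33) and MCCB (1.61 ± 0.25) rose beside SAG29.

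Photosynthesis genes, low in roots, rose there: 6 of 11 at 6 h, 6 at 12 h and 11 at 24 h, against 7, 6 and 11 adjusted over the list alone, with medians of 0.43, 0.53 and 0.84. Camera gave adjusted p of 0.00163, 1.4e-04 and 2.6e-07 (adjusted p = 0.234, 0.168 and 0.0876 with an estimated correlation). RCA rose by 1.86 ± 0.15 at 24 h, from a signal of 80.5 to 315, PSAE-1 by 1.64 ± 0.18, from 37.0 to 133, and LHCB4.1 by 1.06 ± 0.16. Of the other markers of green tissue, PRK was 0.92 ± 0.22 and LHCB4.2 0.69 ± 0.19 higher. PRK did not pass without roots 0.5 h replicate 1 (adjusted p 0.0525) or roots 24 h replicate 1 (0.0916), nor LHCB4.2 without roots 0.5 h replicate 2 (0.0589) or roots 24 h replicate 1 (0.0953).

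Ribosomal protein genes fell in roots at 6 h (11 of 21, 13 adjusted over the list alone), 12 h (13 and 13) and 24 h (19 and 20), with medians of -0.36, -0.45 and -0.59. The camera adjusted p were 0.00163, 1.5e-04 and 7.1e-07 (adjusted p = 0.310, 0.294 and 0.171 with an estimated correlation). AT4G30800 (-1.67 ± 0.18) and AT5G15520 (-1.22 ± 0.22) fell at 24 h. The ABA- and dehydration-induced genes rose less: LEA4-5 by 2.53 ± 0.37, from a signal of 109 to 667, and COR15A by 2.34 ± 0.51 at 24 h, the 2 members called over all genes and adjusted over the list alone. LTI30 (0.55 ± 0.46, 2581 to 3773) and COR47 (0.58 ± 0.25, 1957 to 2952) did not pass. The list's medians were 0.73 at 1 h, 1.14 at 3 h, 0.92 at 6 h, 1.04 at 12 h and 0.58 at 24 h, with camera adjusted p of 0.00283, 2.4e-04, 0.00163, 0.0117 and 0.0337; adjusted p = 0.940, 0.304, 0.234, 0.294 and 0.382 with an estimated correlation. The 24 h list call was lost under quantile normalization, without a pseudocount and with the stricter filter, and the 1 h call in fry (0.743).

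**Figure D3:**
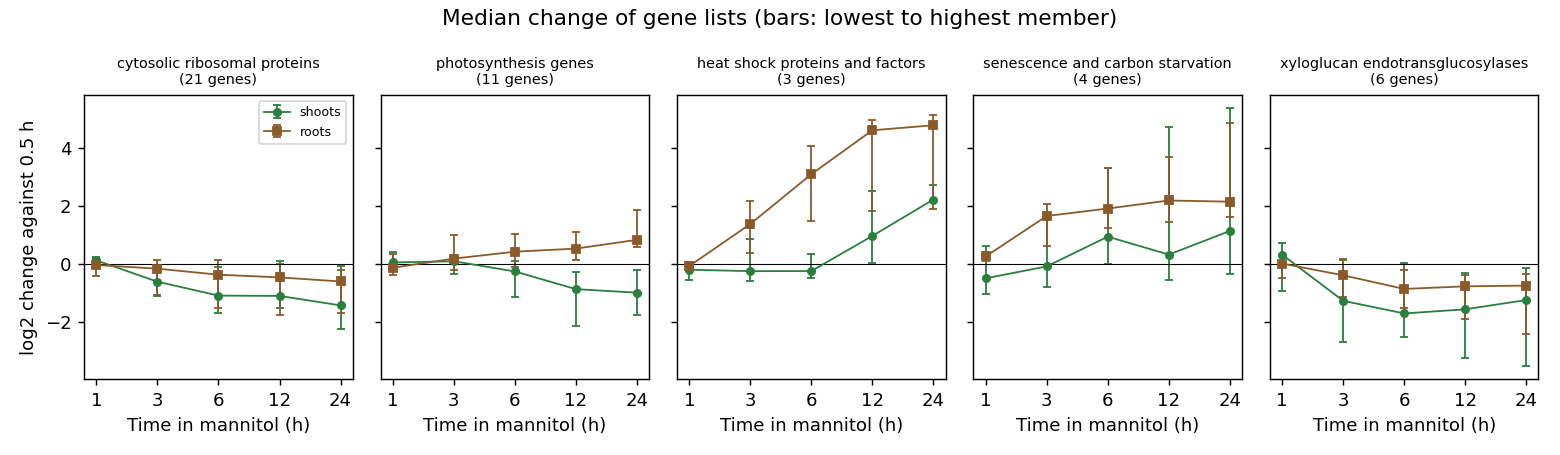
Median log2 change against 0.5 h of 5 gene lists, by hours in mannitol, in shoots and roots, with bars from the lowest to the highest member. At 24 h the photosynthesis median was -0.98 in shoots and 0.84 in roots, and the heat shock median 2.22 and 4.77.

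In roots 3 of 6 xyloglucan endotransglucosylase genes were lower at 24 h, 3 adjusted over the list alone, and the list did not pass (median -0.74, camera adjusted p = 0.0594), with XTH20 at -2.39 ± 0.26. Of 11 expansin genes 2 rose and 5 fell, 7 adjusted over the list alone (median -0.68, adjusted p = 0.295), with EXLB1 up by 3.60 ± 0.33 and EXPA4 down by 2.39 ± 0.28. All 3 cell cycle genes fell at 24 h, 3 adjusted over the list alone: TOPII by 1.53 ± 0.41, AUR2 by 1.33 ± 0.28 and AUR1 by 1.12 ± 0.24 (median -1.33, camera adjusted p = 0.0554). TOPII did not pass without roots 24 h replicate 2 (adjusted p 0.0756). Of 6 auxin-response genes 2 rose and 1 fell, 4 adjusted over the list alone (median 0.15, adjusted p = 0.542). Touch genes had a median of -0.79 (adjusted p = 0.564), with WRKY53 lower by 1.43 ± 0.48, a call lost without either roots 0.5 h replicate (adjusted p 0.0690 and 0.105) or roots 24 h replicate 1 (0.210). Reference genes had a median of -0.05 (adjusted p = 0.728); AT4G26410 was lower by 0.39 ± 0.11, which did not pass without roots 0.5 h replicate 2 (0.0943).

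Lists with fewer than 3 tested genes were read gene by gene. DELTA-OAT, of proline metabolism, rose by 1.94 ± 0.19 in shoots and 2.14 ± 0.19 in roots at 24 h, and AT5G38710 of the same list did not pass (0.13 ± 0.47 and 0.48 ± 0.47). Of glucosinolate synthesis, BCAT4 fell by 1.52 ± 0.29 in shoots, and UGT74B1 did not pass at 24 h (0.39 ± 0.22 in shoots, 0.20 ± 0.22 in roots). EIN3, a regulator of the ethylene response, rose by 0.73 ± 0.11 and 0.65 ± 0.11. GSTU25 of the redox list did not pass (-0.17 ± 0.32 and -0.55 ± 0.32). GI was 1.06 ± 0.13 higher in roots at 3 h. Genes for ABA receptors, their phosphatases, ABA synthesis and breakdown, raffinose synthesis, DREB factors, the morning clock, aquaporins, jasmonate, nutrients, suberin and salicylate were not analysed here.

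At 1 h in roots 124 probe sets passed, 95 higher and 29 lower, and 116 and 14 under median scaling. LEA4-5 (2.36 ± 0.37, adjusted p = 0.00517), AT3G02480 (2.12 ± 0.34, 0.00615) and AT1G16850 (2.11 ± 0.38, 0.0138) rose most. AT1G61840 (-1.45 ± 0.32, 0.0453), GSTU27 (-1.42 ± 0.25, 0.0109) and AT1G10400 (-1.38 ± 0.31, 0.0480) fell most. The count was 197 without roots 1 h replicate 1 and 19 without replicate 2, and 46 and 22 without roots 0.5 h replicates 1 and 2. LEA4-5, AT3G02480 and AT1G16850 were at 3.18, 2.77 and 2.82 without roots 1 h replicate 1 and at 1.54, 1.47 and 1.404 without replicate 2. None of the 6 genes passed without roots 1 h replicate 2 (adjusted p 0.104 for LEA4-5, 0.160 for AT3G02480, 0.3002 for AT1G16850, 0.534 for AT1G61840, 0.196 for GSTU27 and 0.459 for AT1G10400) or without roots 0.5 h replicate 2 (0.0623, 0.106, 0.180, 0.159, 0.113 and 0.270). Without roots 0.5 h replicate 1, LEA4-5 (0.0541), AT1G61840 (0.264), GSTU27 (0.0756) and AT1G10400 (0.213) did not pass. AT1G61840 also missed the threshold without any one shoot array of 0.5, 1, 3, 6 or 12 h or root array of 24 h (0.0505 to 0.0622). AT1G10400 missed it without any one shoot array of 0.5, 3, 6 or 12 h, root array of 6, 12 or 24 h, or roots 1 h replicate 1 (0.0520 to 0.0638). Without a pseudocount LEA4-5 (0.0710), AT3G02480 (0.243), AT1G61840 (0.535) and AT1G10400 (0.320) did not pass. AT1G61840 was also lost under quantile normalization (0.0542), under median scaling (0.0523) and in a fit of root arrays alone (0.0775), and AT1G10400 with a replicate block (0.0530), without a filter (0.0542) and with the stricter filter (0.0583).

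At 3 h AT3G02480 (4.63), AT5G66780 (4.46 ± 0.39) and AT3G17520 (4.44) rose most in roots, and AT1G30870 (-2.98 ± 0.61), AT1G61840 (-2.89) and AT3G01260 (-2.78) fell most. At 6 h the rises were led by AT3G17520 (5.73), AT3G02480 (5.33) and AT5G66780 (4.59) and the falls by AT4G26010 (-3.72 ± 0.62), AT4G11190 (-3.28 ± 0.33) and GSTU20 (-3.14). At 12 h AT3G17520 (6.26), AT5G28520 (5.49) and AT3G02480 (5.39) led the rises, and AT1G52060 (-4.08 ± 0.83), AT5G62340 (-3.71 ± 0.37) and AT4G26010 (-3.62) the falls. Calls numbered 4048 at 3 h (1738 higher, 2310 lower; 2248 and 1644 under median scaling), 5696 at 6 h (2415 and 3281; 2983 and 2587) and 6334 at 12 h (2649 and 3685; 3266 and 2921), so the balance of higher and lower turned with the scaling. AT5G66780 at 3 h was at 3.86 without roots 3 h replicate 1 and at 5.07 without replicate 2, and GSTU20 at 6 h at -2.50 without roots 6 h replicate 1 and at -3.78 without replicate 2. The 3 h count was 2468 and 1955 without roots 0.5 h replicates 1 and 2 and 2070.0 without roots 3 h replicate 1. The 6 h count was 3317 without roots 0.5 h replicate 2 and 3775 without roots 6 h replicate 1. The 12 h count was 4051 without roots 0.5 h replicate 2 and 4200.0 without roots 12 h replicate 2.

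Genes of photosynthesis were among those that differed most between roots and shoots, over all 12 arrays of each tissue. PRK, an enzyme gene of carbon fixation, had a mean signal of 28.1 in roots and 2815 in shoots, a difference of -6.34 ± 0.09 (log2, n = 12 per tissue), and SBPASE (-6.02), LHCB4.2 (-5.92), PIFI (-5.92) and PSAE-1 (-5.88) were likewise lower in roots. All 11 tested photosynthesis genes were lower in roots, 11 adjusted over the list alone (median -5.35, camera adjusted p = 4.8e-11), a call kept with an estimated correlation (adjusted p = 0.0495 with an estimated correlation). ECS1 (-7.81 ± 0.15, signals 11.7 and 4313), AT1G23130 (-7.57, signals 3.92 and 2178), AT1G67865 (-6.65), AT3G28270 (-6.23) and AT1G09310 (-5.87) were also lower in roots; without a pseudocount AT1G23130 lay below ECS1. AT4G39675 stood higher in roots (6.60 ± 0.17, signals 1114 and 3.77), and OSM34, for an osmotin-like protein, was 5.99 ± 0.23 higher.

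Root signals were also higher for AT1G19530 (6.51), AT4G15390 (6.14), AT5G01870 (6.01), AT4G38080 (5.63), AT4G30170 (5.62), AT1G18980 (5.59), AT3G01190 (5.57) and AT1G22440 (5.55), for the root marker PYK10 (3.03 ± 0.07) and for GSTU25 (3.80 ± 0.13). All 21 ribosomal protein genes were higher in roots, 21 adjusted over the list alone (median 0.81, camera adjusted p = 2.6e-04; adjusted p = 0.610 with an estimated correlation). ABA- and dehydration-induced genes went both ways, 3 higher and 2 lower in roots; their median was 0.91, their mean -0.63 and camera's direction down (adjusted p = 0.886). LTI30 was 2.47 ± 0.19 higher and COR15A 4.50 ± 0.21 lower in roots. In all 14141 probe sets passed, 9248 higher in roots and 4893 lower, and the median of all was 0.25; under median scaling, which moved that median to 0.10, 7832 were higher and 5875 lower.

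Some genes changed by 24 h far more in one tissue than in the other, measured as the root change minus the shoot change. AT5G28520 differed by 7.01 ± 0.42 (limma adjusted p = 1.9e-08), with 0.01 in shoots and 7.02 in roots. LTI30 differed by -6.33 ± 0.65, with 6.88 in shoots and 0.55 in roots, and APL4, for a subunit of a starch synthesis enzyme, by -5.91 ± 0.31 (5.27 and -0.64). AT2G42560 (-6.67 ± 0.64), AT1G57590 (-6.52 ± 0.48) and PUB19 (-5.95 ± 0.35) rose in shoots, by 7.17, 6.25 and 4.60, with changes of 0.50, -0.26 and -1.35 in roots. AT2G10940 (5.62 ± 0.67), AT5G48490 (5.53), AT1G33055 (5.52 ± 0.65) and AT1G22690 (5.10) fell in shoots, with changes of -0.75, -0.06, 2.34 and -0.04 in roots. Without shoots 24 h replicate 1 the differences of AT2G10940, AT5G48490, AT1G22690 and AT2G42560 were 4.42, 4.91, 4.097 and -6.06, and without replicate 2 they were 6.81, 6.14, 6.10 and -7.28.

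By list, the ABA- and dehydration-induced genes rose less in roots than in shoots at 24 h, with a median difference of -4.11 (5 of 5 differed, 5 adjusted over the list alone; camera adjusted p = 5.0e-05; adjusted p = 0.247 with an estimated correlation). Photosynthesis genes differed the other way by 2.08, 11 of 11 and 11 adjusted over the list alone (1.5e-10; adjusted p = 0.0574 with an estimated correlation). Ribosomal protein genes fell less in roots by a median of 0.82 (0.50 under quantile normalization; 16 up and 1 down, 18 adjusted over the list alone; 4.8e-06; adjusted p = 0.360 with an estimated correlation). The 24 h changes differed between tissues for 5942 probe sets, 3028 with a higher root change and 2914 with a lower one, and the time courses as a whole for 8271.

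Both tissues shared many calls at 24 h. Probe sets higher in both numbered 1713, where independent lists would share 729, and probe sets lower in both numbered 2450.0, where independent lists would share 1327. Opposite calls numbered 231 (higher in shoots, lower in roots; 1018 by chance) and 377 (lower in shoots, higher in roots; 950.3 by chance). The comparisons share no arrays, but the fit gave each probe set the same estimate of spread in both tissues. Calls in the tissues are therefore not fully independent, and the numbers by chance are only a rough guide. Across genes, which are not independent replicates, the changes of the tissues correlated with r = 0.05 at 1 h, 0.30 at 3 h, 0.43 at 6 h, 0.41 at 12 h and 0.50 at 24 h. The mean root-shoot correlation of signals across probe sets was 0.526 at 0.5 h and 0.667 at 24 h, each over 4 pairings of arrays.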

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

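The test of an equal share of green tissue and the tests of single ABA-induced genes for saturation and for a level already raised in roots were chosen only after their results were seen, and the autophagy and chloroplast-genome groups were tested after the lists were fixed; the other tests in this part were chosen beforehand. The single genes, the counts and the list medians given first were picked because the change in roots differed from the change in shoots in a test of that difference; the closeness of root and shoot profiles and the overall tissue difference were not.

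AT5G28520 (7.01), AT2G10940 (5.62), AT5G48490 (5.53), AT1G33055 (5.52) and AT1G22690 (5.10) had the largest positive differences at 24 h, as the root change minus the shoot change in log2. AT2G42560 (-6.67), AT1G57590 (-6.52), LTI30 (-6.33), PUB19 (-5.95) and APL4 (-5.91) had the largest negative ones. Without shoots 24 h replicate 1 AT2G10940, AT5G48490, AT1G22690 and AT2G42560 were at 4.42, 4.91, 4.097 and -6.06, and without replicate 2 at 6.81, 6.14, 6.10 and -7.28. Differences passed for 709 probe sets at 1 h (424 higher, 285 lower), 3609 at 3 h (1598 and 2011), 4826 at 6 h (2287 and 2539), 5933 at 12 h (2674 and 3259), 5942 at 24 h and 8271 over the whole course. Under median scaling the balance was 2025 higher and 1641 lower at 3 h, 2667 and 2094 at 6 h, and 3291 and 2568 at 12 h, so it turned with the scaling. The 1 h count was 397 and 425 without roots 0.5 h replicates 1 and 2, 465 without shoots 1 h replicate 1 and 371 without roots 1 h replicate 2, and the 3 h count 2372 without shoots 3 h replicate 1.

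The ABA- and dehydration-induced genes had median differences of -2.73 at 3 h, -3.77 at 6 h, -4.73 at 12 h and -4.11 at 24 h (adjusted p = 0.309, 0.212, 0.206 and 0.247 with an estimated correlation). Photosynthesis genes had 0.66 at 6 h, 1.82 at 12 h and 2.08 at 24 h (adjusted p = 0.212, 0.0731 and 0.0574 with an estimated correlation). Ribosomal protein genes had 0.51 at 3 h, 0.78 at 6 h, 0.55 at 12 h and 0.82 at 24 h (adjusted p = 0.396, 0.212, 0.332 and 0.360 with an estimated correlation), and the 3 h and 12 h calls were lost under quantile normalization, with medians of 0.20 and 0.17 and 0.50 at 24 h. Heat shock genes had 2.73 at 6 h and 2.07 at 12 h (adjusted p = 0.212 and 0.293 with an estimated correlation), the latter lost under median scaling and with the stricter filter. Genes of senescence and carbon starvation had 1.39 at 3 h (adjusted p = 0.309 with an estimated correlation). Autophagy genes had 0.18 at 1 h (adjusted p = 0.805 with an estimated correlation), and genes of the chloroplast genome 0.22 at 6 h, 0.64 at 12 h and 0.62 at 24 h (adjusted p = 0.793, 0.740 and 0.716 with an estimated correlation). Under quantile normalization the chloroplast-genome medians were 0.08 at 6 h, which did not pass, and 0.37 at 12 h.

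Photosynthesis genes rose in roots by 24 h, by a median of 0.84, while they fell in shoots, and both list calls were lost with an estimated correlation. Array scaling is argued against: the median was 0.92 under median scaling and 0.97 under quantile normalization. Green shoot tissue in the 24 h root samples met the bound set for it only just. Of 58 other abundant shoot-specific probe sets, 24.1% gained less than 0.5 times the median share of the list, which was 3.03% (the median of the others was 3.25%). A joint rise of chloroplast genes would meet that bound too, and the 58 may hold photosynthesis genes that the annotation does not name. In 7 of 11 members the gain exceeded that of SBPASE in any pairing of root arrays, which counts only weakly against an equal share behind every member. SBPASE was picked as the lowest, and the pairings leave out the spread of the 24 h shoot arrays. Shares ran from 1.09% for SBPASE to 5.89% for LHCB4.1 and 10.8% for LHCB4.3. The 24 h shoot signal of LHCB4.3 was only 179, below the 1000 required of the 58 probe sets. The 69 tested genes of the chloroplast genome showed no such rise in roots, with a median signal of 281 at 0.5 h and 241 at 24 h. Their median in shoots at 24 h was 1286, so green tissue would add to their root signal, but a fall within roots could hide that. A smaller share of green tissue and a rise within roots may both contribute, and neither is excluded.

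Root and shoot profiles came closer, from a mean correlation of 0.526 at 0.5 h to 0.667 at 24 h. Root tissue in the 24 h shoot samples is argued against, since the lower quartile of the share gained by 52 root-specific probe sets was -0.781%, their median was 0.427% and 25 lay at or below 0, though their upper quartile was 18.3%. Weak signals near the floor are argued against by a rise of 0.175 over the 8407 probe sets of highest mean signal. Under quantile normalization the rise was 0.131 beside 0.141. A scale factor on an array hardly alters a correlation of log2 signals, and quantile normalization keeps the ranks within an array. That test could therefore hardly have removed the rise and decides nothing about array scaling. A response to mannitol common to both tissues is a hypothesis that these tests leave open. RNA quality was not tested as an explanation. The first-design actin ratio moved from 6.77 to 16.7 in shoots and from 11.1 to 12.3 in roots. The other actin ratio moved from 2.42 to 2.57 in shoots and from 1.74 to 1.96 in roots. The GAPDH ratio moved from 1.35 to 1.57 in shoots and from 1.104 to 1.34 in roots. Each ratio rose in both tissues.

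ABA- and dehydration-induced genes rose further in shoots than in roots; saturation of the root signal is argued against for the list, whose median root signal at 24 h was 667, against 1976, a level near the top of the signals on the root arrays. LTI30 (3773) and COR47 (2952) lay above that level. Both 3 h root arrays read each of them above both 24 h root arrays, by a ratio of at least 1.16. That argues against a ceiling at their 24 h signal, but it cannot exclude a compression of bright signals. The list's median root minus shoot differences were 2.71 at 0.5 h and -1.71 at 24 h. By the bound set beforehand, the 24 h median argues against a level already raised in roots at 0.5 h behind the pattern. These medians come from different genes that went different ways, so that verdict need not hold for each gene. COR15A (-1.53 to -5.64) and COR15B (-0.17 to -1.71) were not higher in roots at 0.5 h, which argues against a raised start for these genes. LEA4-5 (3.44 to -2.18) ended lower in roots as well, but it was picked for that. It started higher there, so a raised start may account for part of its difference. For COR47 (2.71 to -0.55) and LTI30 (6.04 to -0.29) a raised start stays open. A weaker or earlier response in roots is a hypothesis, and untreated plants, which would show the level before mannitol, were not analysed here.

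Chance is argued against for the difference between roots and shoots. Of 100 splits of the 24 arrays into 2 groups of 12, 1, the real one, gave as many probe sets as its 13234 in a fit with time as a term. This is the smallest share that 100 splits can show, and they were drawn without regard to time. The highest other split gave 12365. That split kept 11 of the 12 root arrays together, which points to a structure of the samples by tissue.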

How the results depend on the processing

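The gene families and the lists of fewer than 3 genes were added after the data were seen, and the other tests in this part were chosen before. Of 20 counts under 657 alternatives 634 stayed within 1.5 times and 23 moved. Of 217 gene changes under 7375 alternatives 7295 kept direction and side of the threshold, 80 lost the call and 0 reversed. Most alternatives for counts and gene changes left out 1 array. Where 2 groups are compared, most arrays lie outside them, and leaving out such an array cannot move or reverse the change. These totals therefore overstate how firmly the results were tested. Of 89 list calls under 979 alternatives 834 held, 145 were lost and 0 reversed.

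The roots 1 h count of 124 was 221 under quantile normalization and 264 with 4 times the pseudocount; the cause was not tested. With single arrays left out, when the lone array of a group is assumed to vary like the other groups, it ran from 19 (without roots 1 h replicate 2) to 197 (without replicate 1), with 46 and 22 without roots 0.5 h replicates 1 and 2. The shoots 1 h count ran from 856 (without shoots 0.5 h replicate 2) to 1536, with 931 and 935 without shoots 1 h replicates 1 and 2. The roots 3 h count ran from 1955 (without roots 0.5 h replicate 2) to 4165, with 2468 without replicate 1 and 2070.0 without roots 3 h replicate 1. The roots 6 h count ran from 3317 (without roots 0.5 h replicate 2) to 5805, with 3775 without roots 6 h replicate 1. The roots 12 h count ran from 4051 (without roots 0.5 h replicate 2) to 6434, with 4200.0 without roots 12 h replicate 2. The tissue difference at 1 h ran from 371 (without roots 1 h replicate 2) to 903, with 397 and 425 without roots 0.5 h replicates 1 and 2 and 465 without shoots 1 h replicate 1. At 3 h it ran from 2372 (without shoots 3 h replicate 1) to 3717. Leaving out an array leaves its group with 1 by construction.

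Of the 49 pathway list calls, 1 held with a correlation estimated from the residuals, that of photosynthesis genes between roots and shoots, and 97 list shifts passed in fry, which does not compare a list with other genes. Of the 89 calls, families included, 79 held under quantile normalization, 83 under median scaling, 79 without a pseudocount, 87 with 4 times the pseudocount, 86 without a filter and 71 with the filter at the 60th percentile.

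With the replicate number as a block, pathway list calls numbered 50, and the shoots 24 h and roots 24 h counts were 9850.0 and 6882. Residuals of the 6 root and shoot pairs with the same time and number correlated between -0.105 and 0.041, which gave no sign that the numbers pair root with shoot samples; over all 66 pairs of groups the correlations ran from -0.165 to 0.348, with 13 above 0.1. Signal over background limits the genes near the floor, whose changes the pseudocount shrinks.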

Other observations

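The gene families in this part, taken from symbols, were tested only after the lists had been fixed and the annotation seen, and the members named were chosen after their values were seen.

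Autophagy genes (ATG) rose in both tissues. Of 8 tested, 7 rose and 1, ATG8E (-1.16 ± 0.19), fell in shoots at 24 h (median 1.11, camera adjusted p = 0.00554; adjusted p = 0.371 with an estimated correlation). In roots 6 of 8 rose at 24 h (median 0.71, adjusted p = 0.00125; adjusted p = 0.168 with an estimated correlation). ATG8H rose by 2.47 ± 0.23 in shoots and 1.63 ± 0.23 in roots, and ATG8E by 0.76 ± 0.19 in roots. Sugar transporter genes (SWEET) rose in roots at 24 h, 6 of 10 (median 0.80, or 0.40 without a filter and 0.48 with 4 times the pseudocount; adjusted p = 0.00217; adjusted p = 0.0518 with an estimated correlation). SWEET13 rose by 3.61 ± 0.29 in roots and 2.43 ± 0.29 in shoots, SWEET4 by 2.05 ± 0.31 and 4.22 ± 0.31, and SWEET2 rose by 2.58 ± 0.24 in roots and fell by 1.21 ± 0.24 in shoots.

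Genes for endoglucanases (GH9) fell in roots at 24 h, 5 of 8 (median -1.16, or -0.59 without a filter; adjusted p = 0.00722; adjusted p = 0.168 with an estimated correlation), with GH9C2 at -2.45 ± 0.25. Genes of wall acetylation (TBL) fell in roots, 8 of 16 (median -0.63, adjusted p = 0.0121; adjusted p = 0.168 with an estimated correlation), with TBL36 at -2.45 ± 0.24. Of 13 IQD genes 7 fell (median -0.62, adjusted p = 0.0197; adjusted p = 0.168 with an estimated correlation), a call lost with the filter at the 60th percentile. Beta-tubulin genes (TUB) fell in roots, 4 of 5 (median -0.88, adjusted p = 0.0258; adjusted p = 0.266 with an estimated correlation), TUB1 by 1.81 ± 0.35 and TUB5 by 1.65 ± 0.27, and TUB5 fell by 2.90 ± 0.27 in shoots.

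Of 69 tested genes of the chloroplast genome 42 fell in shoots at 24 h (median -0.56, adjusted p = 1.6e-04; adjusted p = 0.574 with an estimated correlation), ndhH by 1.83 ± 0.17. All 69 were lower in roots than in shoots (median -2.44, adjusted p = 1.9e-32; adjusted p = 0.208 with an estimated correlation). Genes for glycosyltransferases (UGT) went both ways in shoots at 24 h, 16 of 37 up and 4 down (median 0.44, adjusted p = 0.00554; adjusted p = 0.371 with an estimated correlation), with UGT76E12 at 4.41 ± 0.65, UGT84A3 at 2.65 ± 0.19 and UGT76C2 at -3.24 ± 0.24. Without shoots 24 h replicate 1 UGT76E12 was at 3.74, and without replicate 2 at 5.07. UGT87A2 rose by 2.65 ± 0.26 in shoots and 1.95 ± 0.26 in roots. In roots at 24 h the family had 10 genes up and 3 down (median 0.20, adjusted p = 0.0388; adjusted p = 0.462 with an estimated correlation), a call lost under quantile normalization, under median scaling, without a filter and with the stricter filter. Of 13 beta-glucosidase genes (BGLU) 5 rose and 2 fell in roots (median 0.70, adjusted p = 0.0197; adjusted p = 0.266 with an estimated correlation), BGLU16 by 1.77 ± 0.17 and BGLU24 by 4.89 ± 0.37; the call was lost without a filter, with the stricter filter and without a pseudocount.

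Of 14 cytochrome P450 genes (CYP) 4 were higher and 10 lower in roots than in shoots (median -1.75, adjusted p = 0.0176; adjusted p = 0.409 with an estimated correlation), with CYP71B5 at -3.27 ± 0.10, and the call of the family was lost under median scaling and without a filter, where the median turned to just above 0.

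Of the 11968 probe sets that changed over time in shoots, 3028 had their highest group mean at 1 h, 2659 at 24 h and 2653 at 0.5 h. Of the 7620.0 in roots, 2888 had it at 0.5 h, 1715 at 24 h and 966 at 1 h.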
